A study of Mus musculus with 24 samples.

How the data were processed

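RNA from mouse bone-marrow-derived macrophages was measured as poly-A-selected RNA-seq in 24 libraries, 4 in each of 6 groups. The groups combine 3 siRNA transfections, a control siRNA (siNC) and a pair of siRNAs against Plxdc2 (siPLXDC2-1 and siPLXDC2-2), with either PBS or PTEN protein. Each library was placed in its group from its treatment label. Its title gives a number from 1 to 4, used as the replicate number, and a stem shared by 1 PBS and 1 PTEN library; no label says whether libraries with the same stem came from the same culture.

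The deposited table holds, per the file headers, read counts for every library and FPKM values beside them. The deposited read counts are whole numbers of reads per gene, with no normalization, and all statistics started from them. The deposited FPKM values (reads per kilobase of gene and per 1e6 reads) were checked against the counts: in the 16554 genes where a length could be computed, 99.722% gave a whole-number gene length within a tolerance of 0.001, and 100% gave the same length in all 24 libraries within that relative tolerance. The FPKM values were used for nothing else. Per the submitters' processing notes the tools were fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1, with the mouse build mm39; their order, and the annotation release, strand and multi-mapped read settings, are not given in the sources used here. The table has 21959 genes by Ensembl identifier, and 21851 of these were given a symbol from the GENCODE mouse annotation; 52 identifiers share a symbol and were kept apart, and 108 without a symbol kept their identifier. The table gives no coordinates, so positions are from that annotation on GRCm38.

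Total counts ranged from 17.37 to 26.49 M (M, 1e6) per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11710, and libraries were scaled by TMM, which sets the average gene of each library to no change. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, which left 18 residual degrees of freedom; the common biological coefficient of variation was 5.7% and the prior degrees of freedom 8.29. Contrasts were tested with the quasi-likelihood F test, two-sided, and p-values were adjusted by Benjamini-Hochberg over the 11710 genes within each comparison. A gene was called at an adjusted p under 0.05. Log2 fold changes are given with a standard error (SE) computed back from the test, as the absolute log2 change divided by the square root of F. It is approximate, above all for large changes from few reads. The SEs of separate responses therefore need not combine to the SE of their difference. Levels are given as CPM (counts per 1e6 counts) with TMM scaling, as mean and SD of 4 libraries. Adjusted p-values measure the spread between these libraries. The labels do not say what separates the 4 libraries of a group, so this spread can be partly or wholly technical. Where a group had 1 to 3 reads for a gene the fold is given as a ratio of summed reads with its exact 95% interval; intervals and floors (3 counts) cover counting error only, since the reads carry no molecular identifiers.

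The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. They are PTEN against PBS within each siRNA, the difference of that response between each Plxdc2 siRNA (and the mean of both) and siNC, each Plxdc2 siRNA against siNC in PBS, and one Plxdc2 siRNA against the other in PBS. The difference of the PTEN response between the Plxdc2 siRNAs was added after seeing the data. Named genes follow a rule: in each comparison up to 10 with the highest and up to 10 with the lowest log2 fold change among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries (not asked of the response differences), without predicted or clone names; up to 4 members of smallest p from each list; and a fixed set of 20 genes that includes Plxdc2, Pten, Stat1, Jak2, Nos2, Tnf and Il6. Id1 in both siPLXDC2 arms and Smad6 in the siPLXDC2-1 arm were named after their values were seen, and some genes named for 1 of the siPLXDC2 siRNAs are also given for the other.

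Gene lists covered inflammatory mediators, chemokines, interferon responses, antigen presentation, IL-4 and IL-13 activation, tumour-associated macrophage genes, signalling (JAK-STAT, PI3K-AKT-FOXO), metabolism, stress, cell cycle, ribosome, matrix, macrophage genes and markers of other cells. Of 32 lists, 28 had at least 5 tested members and were tested with camera (preset inter-gene correlation 0.01) in limma 3.58.1, with Benjamini-Hochberg adjustment over the 28, and alongside with an estimated correlation and with fry. The neutrophil (3 tested members), B cell (0), T and NK cell (3) and erythroid and megakaryocyte (4) marker lists were too small for a set test. The summed CPM of each marker list was compared between PTEN and PBS, under siNC and, added after seeing the data, under each Plxdc2 siRNA and without the most abundant gene of each list, by an exact two-sided permutation test, for which the smallest p that 4 against 4 libraries allow is 0.0286.

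The PTEN response was compared between siRNAs by a cross-fit. Genes were called in 2 PTEN and 2 PBS libraries of siNC and then measured in the remaining siNC libraries and in each siPLXDC2 arm, in all 6 choices of the calling libraries, since genes picked for a large change shrink when measured again. The genes called for both Plxdc2 siRNAs in PBS were counted beside the number that independent lists would share, 20 simulations of data with no effect on the same control libraries, and a version in which the siNC PBS libraries were divided 2 and 2 between the comparisons.

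The pipeline was tested on simulated data in 5 runs, with 50 genes changed at each of 4 folds. Changes of 2-fold were recovered in 90.4% of genes for PTEN against PBS under siNC, in 84.4% for a response difference and in 88% for an siRNA against siNC; changes of 1.25-fold were recovered in 62.8%, 36.8% and 55.6%. Among all calls, 5.34%, 5.7% and 4% were false. The simulated libraries were independent, started from the siNC PBS means and had few changed genes. These shares therefore do not cover data in which most genes change or the replicate numbers pair libraries.

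Whether replicate numbers pair the libraries was checked by correlating residuals of genes above a mean log2 CPM of 3. In the comparison of siPLXDC2-2 with siNC in PBS all 4 same-number pairs exceeded 0.1 (lowest 0.124, mean 0.263, against a mean of -0.082 between different numbers), and with the number as a block 4237 genes were called there in place of 3804, 3772 of them shared. In the other comparisons at least 1 pair fell below 0.1, but same-number means (0.162 to 0.25) still lay above those of different numbers (-0.08 to -0.052). Over all groups 39 of 60 same-number pairs exceeded 0.1 (mean 0.174, against -0.057). Residuals were centred within each group, so negative means between different numbers follow from positive same-number means. They are no separate baseline. For 19 of 24 libraries the best match in another group had their own number. The number may therefore group libraries in all comparisons. The group model was kept throughout. No library duplicated another. By the mean chi-square per gene against the other 3 libraries of the group, replicates 4 (20.6) and 2 (18.3) of siPLXDC2-2 in PBS lay farthest, then replicate 2 of siNC in PBS (12.6), the farthest in its group. Alternatives were RLE factors, library totals alone, no low-count filter, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number or title stem as a block, each library left out in turn, and, added after seeing the data, leaving out 2 of these libraries together, replicate 4 of siPLXDC2-2 with either of the others. Alternatives planned for a table of normalized values were not needed, since counts were deposited. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.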

Results

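Gene expression was measured by poly-A RNA-seq in macrophages grown from C57BL/6J mouse bone marrow with M-CSF for 7 days. The series text describes an M2-like polarization by the cytokines IL-4 and IL-13 over 48 h, while the sample labels call the cells naive. Cells received a control siRNA (siNC) or 1 of 2 siRNAs against Plxdc2 (siPLXDC2-1 and siPLXDC2-2). They were then given either PBS or PTEN protein at 100 ng/mL for 24 h. PTEN is a phosphatase and tumour suppressor that opposes PI3K signalling inside cells, and Plxdc2 encodes a transmembrane protein with a plexin domain. Each of the 6 groups had 4 libraries. Mean depth (SD, n = 4) was 23.5 ± 0.93 M counts (M, 1e6) for siNC with PBS and 23.8 ± 2.51 M for siNC with PTEN. It was 21.5 ± 2.1 M and 18.6 ± 1.38 M for siPLXDC2-1, and 23.7 ± 2.07 M and 22.5 ± 2.18 M for siPLXDC2-2, in the same order. The first principal component held 76.4% of the variance.

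The first question was whether the siRNAs lowered their target. Plxdc2 (ENSMUSG00000026748; chromosome 2, 16356304 to 16755839 on GRCm38, plus strand) fell with both siRNAs in PBS. Its level was 119 ± 10.7 CPM (SD, n = 4) with siNC, 6.80 ± 0.889 with siPLXDC2-1 and 7.66 ± 3.40 with siPLXDC2-2, that is 5.73% and 6.44% of the siNC level. The log2 change was -4.12 ± 0.16 (SE) with siPLXDC2-1 (edgeR quasi-likelihood, adjusted p = 1.87e-16) and -3.93 ± 0.16 with siPLXDC2-2 (adjusted p = 2.60e-16). All 4 libraries lay below all 4 siNC libraries in each case. The 2 siRNAs were not distinguishable at this gene (log2 difference -0.19 ± 0.20, adjusted p = 0.52). In PTEN-treated cells Plxdc2 stood at 126 ± 13.2 CPM with siNC, 4.51 ± 0.903 with siPLXDC2-1 and 4.01 ± 1.14 with siPLXDC2-2, so the knockdown was present in both treatments.

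**Figure D1:**
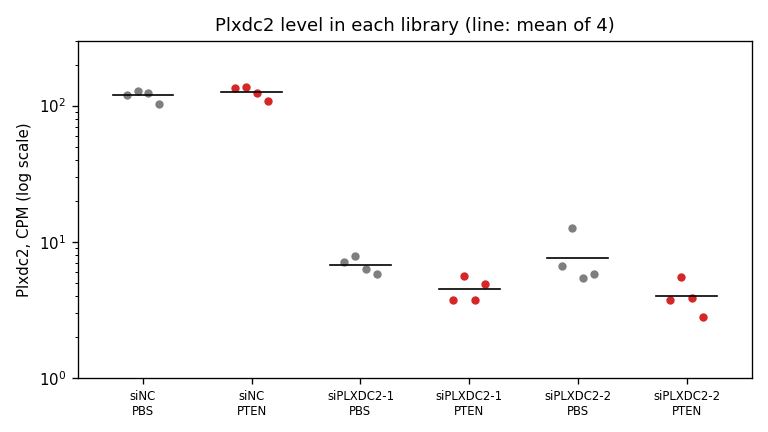
Plxdc2 level in CPM (log axis) in each of the 24 libraries by group, with points for libraries and a line at the mean of 4. The siNC means are 119 and 126 CPM, and the siPLXDC2 means lie between 4.01 and 7.66 CPM.

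The central comparison asked what added PTEN protein does to macrophages that keep Plxdc2. The only comparison was with PBS, and the design has no control for endotoxin or other components of the protein preparation. Effects of PTEN are therefore those of the preparation as added. Under siNC, PTEN raised the genes of classical inflammatory activation by large factors. Il6 (ENSMUSG00000025746), an inflammatory cytokine, went from 0.283 CPM to 620 ± 102 CPM (SD, n = 4), a log2 change of 11.06 ± 0.17 (SE). Tnf (ENSMUSG00000024401), another inflammatory cytokine, rose from 31.1 to 3729 ± 506 CPM, and Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, from 1.89 to 1043 CPM. Il1b went from 3.23 to 2032 CPM. Cnr2, the cannabinoid receptor of immune cells, fell from 79.9 to 0.891 CPM.

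Of 11710 genes tested, 9673 were called for PTEN under siNC by edgeR, 4645 higher and 5028 lower. Of them 4000 changed at least 2-fold (1686 up, 2314 down). Beside Il6 the highest changes included Ptgs2, the inducible cyclooxygenase (10.55 ± 0.20), Edn1, which encodes endothelin (10.53 ± 0.12), Gfi1, a transcriptional repressor (10.41 ± 0.22), and Il12b, a subunit of IL-12 and IL-23 (10.38 ± 0.21). The chemokine genes Ccl22 (9.98 ± 0.16) and Cxcl3 (9.81 ± 0.28) followed. Il12a had only 2 reads over the siNC PBS libraries and was 2670-fold higher with PTEN (exact 95% interval 740 to 22100). The lowest included Arhgap19 (-6.58 ± 0.14), Cnr2 (-6.46 ± 0.10), Zfp395 (-6.42 ± 0.18), and Rasgrp3 (-6.01 ± 0.14). Next were Lpin1, a phosphatidate phosphatase (-5.91 ± 0.16), and the peroxisomal transporter gene Abcd2 (-5.80 ± 0.08). Among these genes the smallest adjusted p was 8.3e-30, for Edn1, and the largest 2.01e-22, for Cxcl3. The genes with the highest and lowest changes were named among those with all 4 PTEN libraries on one side of all 4 PBS libraries. Of the other called genes named here Arg1 alone had overlapping libraries.

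All 33 tested inflammatory and NF-kB genes rose under siNC (33 adjusted over the list alone), with a median log2 change of 5.38, also with genes of 3 reads or fewer in a group set at 3 reads (camera adjusted p = 2.28e-36). They included Il1b (9.30 ± 0.17), Tnf (6.91 ± 0.10), the costimulatory receptor gene Cd40 (6.88 ± 0.10), the NF-kB inhibitor gene Tnfaip3 (5.21 ± 0.07) and the inflammasome gene Nlrp3 (4.73 ± 0.07). Of 22 chemokine genes 20 rose and 2 fell, and the same numbers held adjusted over the list alone (adjusted p = 5.77e-11). Cxcl1 (9.65 ± 0.20), Cxcl2 (8.72 ± 0.14) and Ccl3 (6.29 ± 0.13) were among them. Of 29 JAK-STAT pathway genes 24 rose and 3 fell (24 and 3 adjusted over the list alone; adjusted p = 4.41e-08). The cytokine feedback inhibitor Socs3 changed by 8.38 ± 0.15, the kinase genes Jak2 (ENSMUSG00000024789) by 3.68 ± 0.06 and Pim1 by 2.41 ± 0.04, Stat3 by 1.69 ± 0.04 and Stat1 (ENSMUSG00000026104) by 1.13 ± 0.05. These 3 calls held with an estimated correlation (adjusted p = 0.000686, 0.0134 and 0.00171).

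Interferon-response and antigen-presentation genes rose as well. Of 34 interferon-gamma and STAT1 target genes 32 rose and 1 fell, the same adjusted over the list alone. Cxcl10 stood at 6.45 ± 0.27, the guanylate-binding protein gene Gbp5 at 6.33 ± 0.11, Cxcl9 at 6.17 ± 0.34, Batf2 at 3.70 ± 0.06 and Cd274, which encodes PD-L1, at 2.26 ± 0.09. The camera adjusted p was 8.96e-20, and with an estimated correlation the adjusted p was 0.0506. Of 34 type I interferon-response genes 33 rose, or 34 adjusted over the list alone (camera adjusted p = 2.61e-19, adjusted p = 0.12 with an estimated correlation). Among them were Mx2 (2.72 ± 0.06) and the RNA sensor gene Ifih1 (2.55 ± 0.06). Of 21 MHC class I presentation genes 19 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 7.93e-07, adjusted p = 0.248 with an estimated correlation). The proteasome activator gene Psme2 (2.27 ± 0.05) and the peptide transporter gene Tap2 (2.19 ± 0.05) were among those that rose. The costimulatory genes Cd86 (2.45 ± 0.11) and Cd80 (2.20 ± 0.09) rose, as did the anti-inflammatory cytokine gene Il10 (1.61 ± 0.11). The lists share members, such as Nos2 and Cd40, so they are not independent.

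Of 42 cell cycle genes 37 fell and 4 rose under siNC, the same adjusted over the list alone, with a median of -1.68 (camera adjusted p = 0.0025, adjusted p = 0.658 with an estimated correlation), and the call was lost with library totals alone. The centromere protein gene Cenpa fell by 4.79 and the cell cycle transcription factor gene E2f2 by 4.61, while the spindle gene Tpx2 (3.18 ± 0.10) and the cyclin gene Ccne1 (2.70 ± 0.10) rose. Among 21 macrophage genes 8 rose and 10 fell, and no shift of the group was called (adjusted p = 0.265). The lineage transcription factor genes Cebpa (-4.39 ± 0.08) and Mafb (-3.56 ± 0.07) fell and Spi1 (1.55 ± 0.04) rose. In the list of 37 genes of IL-4 and IL-13 activation 13 rose and 17 fell, the median was -0.31 and the mean 0.56, opposite in sign, and camera gave an adjusted p of 0.66. Mrc1, the mannose receptor, fell from 826 to 345 CPM (-1.26 ± 0.06). Pparg (-2.95 ± 0.12) and Ptgs1 (-2.39 ± 0.08) fell, while the arginine transporter gene Slc7a2 (4.95 ± 0.16) rose. Arg1, the arginase gene, stood at 0.580 CPM in PBS and 0.280 CPM with PTEN (-1.02 ± 0.44, adjusted p = 0.0335); the call was lost without replicate 1 (-0.72), 2 (at a fold close to the full one) or 3 (-0.82) of the PTEN group or replicate 3 of the PBS group (-0.60), with adjusted p = 0.139, 0.0631, 0.0982 and 0.215. It was also lost, at folds close to the full one, with DESeq2 (-1.01, adjusted p = 0.0725), the title stem as a block (adjusted p = 0.0509) and only the groups compared (-1.03, adjusted p = 0.0973). Retnla (-0.22 ± 0.16, adjusted p = 0.201) and Chil3 (-0.26 ± 0.13, adjusted p = 0.0703) were not called. Retnla was called without PBS replicate 4 (-0.35), and Chil3 was without PTEN replicate 1 (-0.39) or 3 (-0.32) or PBS replicate 4 (-0.38). Chil3 was also called with the replicate number as a block (adjusted p = 0.0337), the title stem as a block (0.00958) and no low-count filter (0.0373), and both genes were with library totals alone (-0.69 for Retnla, -0.73 for Chil3). The Pten transcript itself (ENSMUSG00000013663; chromosome 19, 32757497 to 32826160 on GRCm38) fell slightly, by 0.43 ± 0.04, and Plxdc1, the paralog of Plxdc2, fell by 2.70 ± 0.07. Plxdc2 did not pass the test (0.08 ± 0.12, adjusted p = 0.552), and with library totals alone its change was -0.39 (adjusted p = 0.00458).

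The remaining lists were not called as groups by camera under siNC. Counts that rose and fell were 13 and 15 of 31 tumour-associated macrophage genes, 15 and 19 of 35 PI3K-AKT-FOXO genes, 3 and 14 of 20 LXR and lipid efflux genes (4 and 14 adjusted over the list alone), 15 and 5 of 25 cholesterol synthesis genes, and 13 and 27 of 45 lysosome and phagocytosis genes. They were 13 and 8 of 26 glycolysis and hypoxia genes (11 and 13 with library totals alone), 15 and 5 of 25 genes of the unfolded protein and integrated stress responses (10 and 12 with library totals alone), 7 and 10 of 19 NRF2 genes, 13 and 5 of 19 immediate-early and heat shock genes, and 14 and 6 of 27 matrix and cytoskeleton genes. Median and mean had opposite signs for tumour-associated macrophage genes (-0.09 and 0.17), lysosome and phagocytosis genes (-0.23 and 0.01) and fibroblast and endothelial markers (-0.25 and 0.81), and the NRF2 genes had a median of -0.35 and a mean of 0.00. Inpp5d, the lipid phosphatase SHIP1 (-3.19 ± 0.06), and the transcription factor gene Foxo3 (-2.47 ± 0.07) fell within the PI3K-AKT-FOXO list. The immediate-early genes Jun (-3.27 ± 0.05) and Fos (-2.55 ± 0.09) fell, and the matrix-related genes Serpine1 (6.98 ± 0.12) and Mmp13 (5.84 ± 0.14) rose. MHC class II genes (8 up, 3 down of 13), nuclear oxidative phosphorylation genes (23 up, 6 down of 39), mitochondrially encoded genes (4 up, 0 down of 10, with 3 up over the list alone) and ribosomal protein genes (28 up, 3 down of 46, with 27 up over the list alone) had medians of 0.26, 0.19, 0.14 and 0.12, which turned to -0.21, -0.28, -0.33 and -0.36 with library totals alone.

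Summed marker lists of other cell types moved with PTEN under siNC, and most sums rest on 1 gene. The neutrophil sum went from 198 ± 12.4 to 419 ± 8.23 CPM (SD, n = 4; exact permutation test, p = 0.0286, the smallest possible, adjusted p = 0.0358), but Csf3r made up 98.6% and 99.4% of it. Without Csf3r it was 2.76 and 2.52 CPM (exact permutation p = 0.514). The fibroblast and endothelial sum rose from 43.7 ± 10.9 to 337 ± 20 CPM, with Kdr as 77.1% and 84.6% of it, and from 10 to 51.9 CPM without Kdr. The T and NK cell sum rose from 18.3 ± 3.44 to 26.6 ± 2.1 CPM, with Cd4 as 98.7% and 46.5% of it, and from 0.239 to 14.2 CPM without Cd4. Mast cell, basophil and eosinophil markers rose from 20.1 ± 2.81 to 159 ± 2.34 CPM, or from 19.7 to 39.9 CPM without Hdc, and dendritic cell markers from 710 ± 45.7 to 1210 ± 89.8 CPM, or from 363 to 600 CPM without Bst2. Osteoclast markers fell from 1230 ± 91.3 to 560 ± 18.1 CPM, or from 265 to 161 CPM without Atp6v0d2. The monocyte progenitor sum fell from 719 ± 12.3 to 547 ± 25.8 CPM but rose from 142 to 299 CPM without Cd93, and the erythroid and megakaryocyte sum fell from 98.8 ± 7.15 to 51.6 ± 2.58 CPM but rose from 7.95 to 17.9 CPM without Vwf. For each of these lists but the neutrophil one the exact permutation p was 0.0286 with and without the named gene (adjusted p = 0.0358). B cell markers (0.793 against 1.11 CPM, exact permutation p = 0.257) did not pass the test. Macrophage genes did not either (35200 against 32900 CPM, exact permutation p = 0.0571), but without Lyz2 they fell from 26300 to 24800 CPM (exact permutation p = 0.0286, adjusted p = 0.0358). Single members rose strongly, such as Hdc, the histidine decarboxylase gene (8.15 ± 0.15), and Fscn1, the actin-bundling protein gene (8.45 ± 0.21). As tested lists, 6 and 2 of 10 dendritic cell, 2 and 2 of 5 mast cell, 2 and 6 of 9 osteoclast, 5 and 1 of 11 fibroblast and endothelial, and 3 and 2 of 7 monocyte progenitor markers rose and fell. None of these lists was called by camera, and the mast cell and monocyte progenitor medians (0.03 each) became -0.44 with library totals alone.

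Directions are relative to the average gene. Library totals alone shift all genes by a median of -0.47 (log2) in this comparison, and the share of called genes that were higher went from 48% to 25%.

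**Figure D2:**
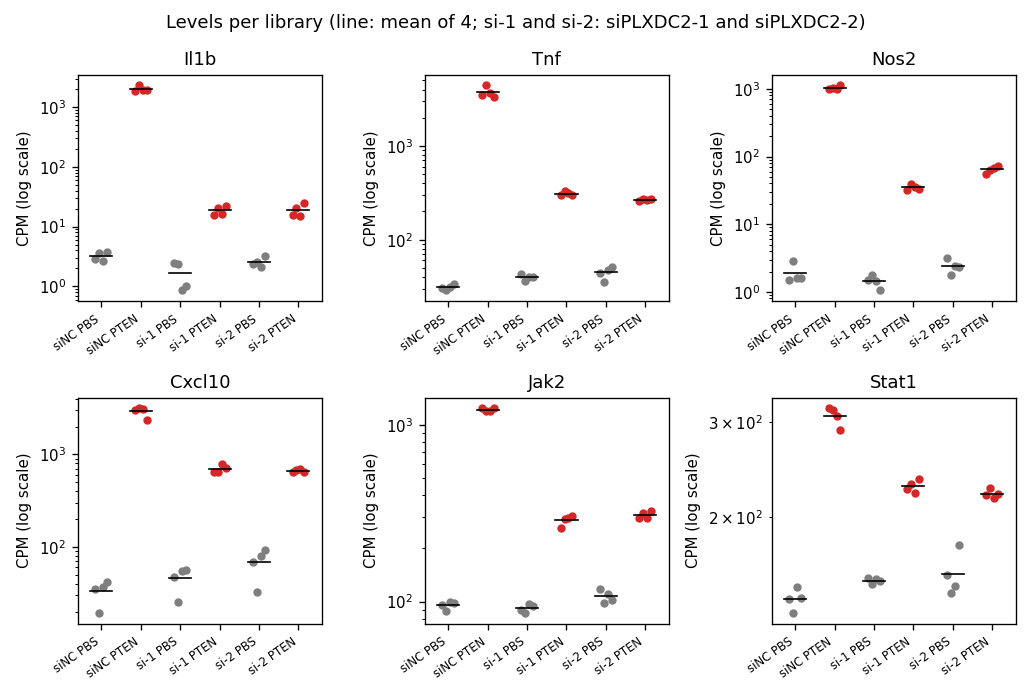
CPM (log axis) of Il1b, Tnf, Nos2, Cxcl10, Jak2 and Stat1 in each library by group, with points for libraries, a line at the mean of 4, and si-1 and si-2 for siPLXDC2-1 and siPLXDC2-2. With PTEN, Tnf reached 3729 CPM under siNC, 311 under siPLXDC2-1 and 267 under siPLXDC2-2, and Nos2 reached 1043, 35 and 64.9 CPM.

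The same PTEN treatment in cells with lowered Plxdc2 asked which part of the response takes place there. Inflammatory genes still rose with PTEN under both siRNAs, by smaller factors. Il6 reached 3.57 ± 0.573 CPM under siPLXDC2-1 and 3 ± 0.452 CPM under siPLXDC2-2 (SD, n = 4), a log2 change of 4.61 ± 0.42 and 3.51 ± 0.36. Nos2 changed by 4.58 ± 0.15 and 4.73 ± 0.12, Tnf by 2.97 ± 0.09 and 2.58 ± 0.09 (adjusted p = 7.68e-20 and 7.87e-19), and Jak2 by 1.66 ± 0.06 and 1.53 ± 0.06. Id3, an inhibitor of basic helix-loop-helix transcription factors, rose to 52.7 ± 3.6 and 69.4 ± 4.55 CPM under the Plxdc2 siRNAs and stood at 2.81 and 3.24 CPM without and with PTEN under siNC.

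Under siPLXDC2-1 edgeR called 5545 genes for PTEN, 2797 higher and 2748 lower, with 720 changed at least 2-fold. Under siPLXDC2-2 it called 5580, 2670 higher and 2910 lower, with 690 changed at least 2-fold. With library totals alone the counts higher and lower were 1918 and 3962 under siPLXDC2-1, and 1921 and 3960 under siPLXDC2-2. With siPLXDC2-1 the highest changes included Lad1 (6.24 ± 0.16), the formyl peptide receptor genes Fpr1 (5.89 ± 0.53) and Fpr2 (5.03 ± 0.31), Cxcl1 (5.81 ± 0.31), the fatty acid receptor gene Gpr84 (5.32 ± 0.18). Id3 (4.99 ± 0.14) and Cxcl2 (4.66 ± 0.13) followed. With siPLXDC2-2 they included Lad1 (5.55 ± 0.15), Smad6, an inhibitor of BMP signalling (5.18 ± 0.22), Id3 (5.07 ± 0.13), Fpr1 (4.88 ± 0.45) and Bcl2a1a, an anti-apoptotic gene (4.16 ± 0.15). Genes that fell in both arms included Etl4 (-2.88 and -2.87), Sox4 (-2.62 and -2.32), Rnf150 (-2.58 and -2.36) and the prostaglandin dehydrogenase gene Hpgd (-2.31 and -2.92). Others were the scavenger receptor gene Cd163 (-2.09 and -1.87), Zfp395 (-1.76 and -2.13) and the lectin gene Clec10a (-1.66 and -1.95). Mrc1 fell in both (-0.61 ± 0.05 and -0.54 ± 0.05). Of the called genes named for these arms Plxdc2 under siPLXDC2-2 alone had overlapping PTEN and PBS libraries.

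Of 33 inflammatory and NF-kB genes 27 rose and 1 fell under siPLXDC2-1, and 30 rose and 1 fell under siPLXDC2-2, with the same counts adjusted over the list alone. Medians were 2.11 and 2.04, or 2.08 and 2 with genes of 3 reads or fewer set at 3 reads. Il1b rose by 3.52 and 2.89 and Il12b by 3.91 and 4.05. Chemokine genes, Cxcl10 among them (3.92 and 3.30), rose in 16 and 17 of 22 cases (17 and 17 adjusted over the list alone), and JAK-STAT genes in 16 and 17 of 29, with 4 and 5 lower (the same adjusted over the list alone). These 3 lists were called in both arms and held with an estimated correlation (adjusted p = 0.000356, 0.00108 and 0.00213 under siPLXDC2-1, and 0.000204, 0.000946 and 0.00597 under siPLXDC2-2). Interferon-gamma and STAT1 target genes rose in 28 and 29 of 34 cases (29 and 29 adjusted over the list alone), with adjusted p = 0.00566 and 0.0107 with an estimated correlation. Type I interferon genes rose in 33 and 32 of 34 (33 and 32 adjusted over the list alone), with adjusted p = 0.0384 and 0.0705 with an estimated correlation. MHC class I genes rose in 16 and 16 of 21 (17 and 16 adjusted over the list alone), and those calls were lost with an estimated correlation (adjusted p = 0.189 and 0.288). Stat1 changed by 0.58 ± 0.05 and 0.49 ± 0.05 and Cd274 by 0.92 ± 0.09 and 0.82 ± 0.09.

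Of 42 cell cycle genes 4 rose and 4 fell under siPLXDC2-1 (median 0.08, or 0 with library totals alone) and 4 rose and 10 fell under siPLXDC2-2 (median -0.04). The camera adjusted p was 0.761 and 0.463. Of 9 osteoclast markers, 2 rose and 4 fell under siPLXDC2-1 and 0 rose and 4 fell under siPLXDC2-2 (camera adjusted p = 0.0268 and 0.0174, and with an estimated correlation adjusted p = 0.0588 and 0.0465). PI3K-AKT-FOXO genes were called lower under siPLXDC2-1 (8 up, 20 down of 35, or 21 down over the list alone, camera adjusted p = 0.00387, adjusted p = 0.135 with an estimated correlation). Under siPLXDC2-2 they missed the threshold (10 up, 18 down, camera adjusted p = 0.0641). NRF2 genes were called higher under siPLXDC2-2 (12 up, 0 down of 19, or 13 up over the list alone, camera adjusted p = 0.0253, adjusted p = 0.76 with an estimated correlation). Under siPLXDC2-1 they missed it (11 up, 0 down, median 0.38 against 0.33, camera adjusted p = 0.0622). Arg1 (-0.20 with adjusted p = 0.718, and 0.56 with adjusted p = 0.331) and Il10 (0.26 with adjusted p = 0.0861, and -0.20 with adjusted p = 0.18) were not called in the siPLXDC2-1 and siPLXDC2-2 arms. Il10 was called under siPLXDC2-1 with only the groups compared (0.25) and without replicate 2 of PTEN (0.32), and under siPLXDC2-2 without replicate 3 of PBS (-0.29). Plxdc2 fell further with PTEN, by 0.60 ± 0.24 under siPLXDC2-1 (adjusted p = 0.0401) and by 0.95 ± 0.22 under siPLXDC2-2 (adjusted p = 0.00086). The first of these Plxdc2 calls was lost without replicate 1 (-0.57) or 2 (-0.52) of the siPLXDC2-1 PBS group or replicate 1 (-0.52), 3 (-0.52) or 4 (-0.64) of its PTEN group, and with limma-voom (-0.60, adjusted p = 0.0658).

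In the siPLXDC2-1 arm 6 marker sums passed the same test with PTEN after adjustment. For sums at the smallest possible p, passing after adjustment depends on how many of them reach that p. Without the most abundant gene of each list fewer did, and none passed (exact permutation test, smallest adjusted p = 0.0953). The neutrophil sum rose from 152 to 201 CPM, with Csf3r as 98.7% of it with PTEN, dendritic cell markers from 696 to 788 (Bst2 63.3%), mast cell, basophil and eosinophil markers from 30.2 to 40 (Hdc 11.7%), and fibroblast and endothelial markers from 67 to 101 (Kdr 90.7%). Osteoclast markers fell from 1280 to 848 CPM (Atp6v0d2 69.7%) and monocyte progenitor markers from 449 to 279 (Cd93 67.3%; exact permutation p = 0.0286, adjusted p = 0.0477 for each of the 6). Without the most abundant gene the exact permutation p was still 0.0286 for osteoclast (301 to 257 CPM), monocyte progenitor (106 to 91.2) and erythroid and megakaryocyte markers (9.67 to 15.9). In the siPLXDC2-2 arm fewer sums reached the smallest possible p, and for that reason none passed the threshold after adjustment. This does not show a weaker change than in the siPLXDC2-1 arm. Osteoclast markers stood at 849 and 580 CPM without and with PTEN, monocyte progenitor markers at 792 and 527, neutrophil markers at 209 and 270, mast cell, basophil and eosinophil markers at 16.6 and 26, and fibroblast and endothelial markers at 56.2 and 90.1 (exact permutation p = 0.0286, adjusted p = 0.0572 for each). Dendritic cell markers were at 740 and 787 CPM there (exact permutation p = 0.143, adjusted p = 0.238). Without the most abundant gene, osteoclast markers stood at 270 and 215 CPM in this arm and erythroid and megakaryocyte markers at 9.04 and 14.4. Mast cell, basophil and eosinophil markers were at 16.1 and 22.1 CPM (exact permutation p = 0.0286, adjusted p = 0.0953 for each).

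**Figure D3:**
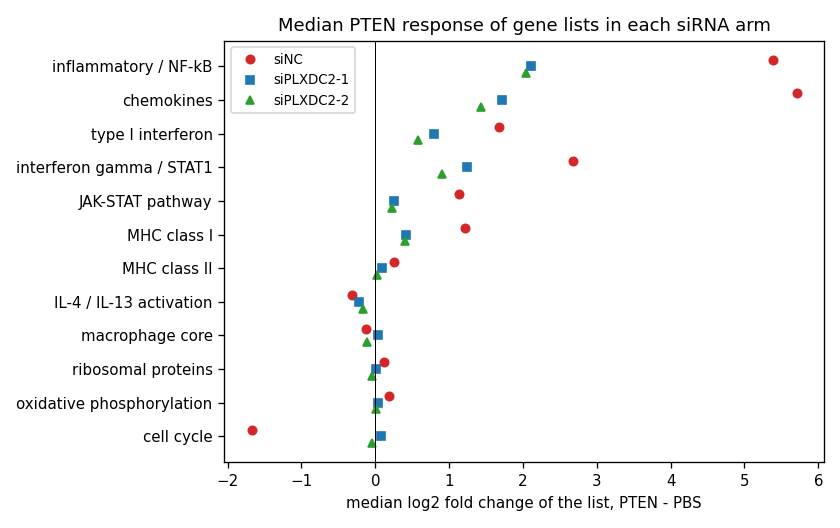
Median log2 fold change, PTEN minus PBS, of 12 gene lists under siNC (circles), siPLXDC2-1 (squares) and siPLXDC2-2 (triangles). The inflammatory and NF-kB list has medians of 5.38, 2.11 and 2.04, and the cell cycle list -1.68, 0.08 and -0.04. With library totals alone the siNC medians of MHC class II, oxidative phosphorylation and ribosomal protein genes change sign.

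The study's main question, whether Plxdc2 knockdown alters the response to PTEN, was tested directly as the difference of the PTEN effects. The inflammatory response was smaller under both siRNAs. Averaged over both, the log2 response fell short of that under siNC by -6.99 ± 0.79 (SE) for Il6, -6.09 ± 0.29 for Il1b, -4.46 ± 0.21 for Nos2, -4.13 ± 0.11 for Tnf, -2.08 ± 0.07 for Jak2 and -0.59 ± 0.06 for Stat1, with 4 libraries in each of 6 groups (adjusted p from 5.07e-22 for Tnf to 9.59e-09 for Il6). Genes that PTEN lowered under siNC were lowered less: the difference was 5.47 ± 0.16 for Arhgap19, 5.38 ± 0.12 for Cnr2 and 4.86 ± 0.10 for Abcd2. Plxdc1 (2.70 ± 0.09) stood at 43.0 and 6.65 CPM under siNC and at 38.9 and 38.2 CPM under siPLXDC2-1.

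For the mean of both siRNAs 8501 genes had a different PTEN response by edgeR, 4364 higher and 4137 lower. For siPLXDC2-1 alone there were 8013 (4136 higher, 3877 lower) and for siPLXDC2-2 alone 8114 (4131 higher, 3983 lower). The differences were of like size with each siRNA. For siPLXDC2-1 and siPLXDC2-2 they were -6.44 ± 1.11 and -7.54 ± 0.85 for Il6, -3.94 ± 0.12 and -4.33 ± 0.12 for Tnf, -4.53 ± 0.29 and -4.38 ± 0.23 for Nos2, and -2.02 ± 0.08 and -2.15 ± 0.08 for Jak2. Between the 2 siRNAs the PTEN response differed in 13 genes (10 higher and 3 lower with siPLXDC2-1). This count depends on the method: it was 44 with DESeq2, 49 and 52 with the replicate number and the title stem as a block, and 7 to 22 with a library left out. Only Itgal, an integrin gene singled out after its value was seen, differed at least 2-fold there (1.02 ± 0.14, adjusted p = 0.00128). A few genes rose with PTEN under the Plxdc2 siRNAs alone: the response difference was 4.84 ± 0.23 for Id3 (adjusted p = 9.78e-17) and 5.25 ± 0.53 for Smad6 (adjusted p = 1.09e-09).

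Of 33 inflammatory and NF-kB genes 30 had a lower and 0 a higher response with the mean of both siRNAs, and of 29 JAK-STAT genes 25 were lower and 3 higher, each the same adjusted over the list alone. Both calls held with an estimated correlation (adjusted p = 0.00151 for each). Among these, Il12b (-6.40 ± 0.75), Cd40 (-4.16 ± 0.11), Tnfaip3 (-3.23 ± 0.08), Stat5a (-2.69 ± 0.08), Pim1 (-1.99 ± 0.05) and Stat3 (-1.63 ± 0.05) were lower. Of 22 chemokine genes 19 were lower and 2 higher, with Ccl3 at -4.69 ± 0.14, Cxcl2 at -4.45 ± 0.16 and Ccl4 at -3.60 ± 0.15 (camera adjusted p = 3.11e-06, adjusted p = 0.104 with an estimated correlation). Type I interferon genes were lower in 33 of 34 cases (median -0.97), with Mx1 at -1.91 ± 0.09 and Ifih1 at -1.71 ± 0.06. Interferon-gamma and STAT1 targets were lower in 31 of 34 with 1 higher (median -1.64), with Cxcl10 at -2.84 ± 0.28 and Cd274 at -1.39 ± 0.11. MHC class I genes were lower in 19 of 21 cases. These last 3 lists had camera adjusted p of 2.06e-14, 3.55e-14 and 1.09e-05, and with an estimated correlation adjusted p = 0.249, 0.141 and 0.363. Cell cycle genes had a higher response in 35 of 42 cases and a lower one in 4 (median 1.58, camera adjusted p = 6.48e-05, adjusted p = 0.608 with an estimated correlation). Kif23 (4.50 ± 0.23), E2f2 (3.66 ± 0.14) and Mcm2 (2.42 ± 0.12) were higher and Ccne1 (-2.44 ± 0.14) lower. Counts for these 5 lists adjusted over the list alone were 19, 33, 31, 19 and 36. Cebpa (3.21 ± 0.09), Mafb (2.67 ± 0.08), Jun (2.82 ± 0.06) and Mrc1 (0.68 ± 0.07) fell less with PTEN under the Plxdc2 siRNAs, and Fos (3.54 ± 0.11), which fell under siNC, rose by 0.93 under siPLXDC2-1 and 1.06 under siPLXDC2-2.

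The size of the remaining response was measured in libraries that had not been used to choose the genes. A mean of 8680 genes was called in 2 PTEN and 2 PBS libraries of siNC. In the remaining siNC libraries these genes changed in the called direction by a median of 0.857 (log2; range 0.805 to 0.897 over 6 choices), against 0.210 under siPLXDC2-1 (SD 0.018 over 4 pairs of PBS and PTEN libraries with the same title stem) and 0.197 under siPLXDC2-2 (SD 0.028). The arms thus kept 24.5% and 23% of the siNC response, or 23.8% ± 2.68 on average. The change was smaller than under siNC in 96.0% and 95.7% of these genes, and its sign was kept in 86.7% and 85.3%. Genes that rose had medians of 0.757 under siNC, 0.192 and 0.168, and genes that fell 0.956, 0.227 and 0.226. The share kept was 23.8% and 23.7% for genes that rose and fell, but 31.0% and 20.3% with library totals alone. For the 100 genes of smallest p the share was 37.1%, with medians of 4.48 under siNC, 1.72 under siPLXDC2-1 and 1.61 under siPLXDC2-2. In the response differences library totals alone shift all genes by 0.39 for siPLXDC2-1, 0.40 for siPLXDC2-2 and 0.40 for their mean, where the share of higher genes went from 51.3% to 77.4%.

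**Figure D4:**
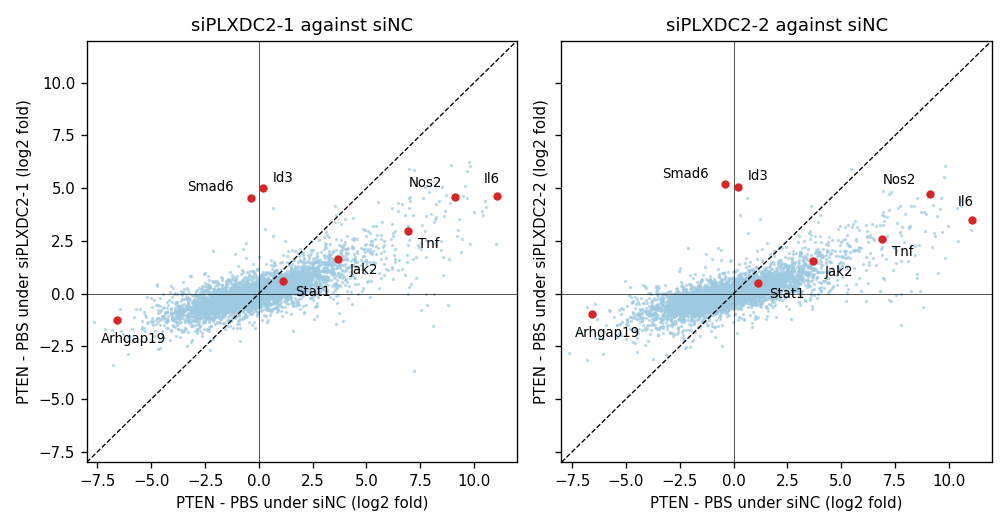
Log2 fold change by PTEN of each tested gene under siNC (horizontal axis) and under siPLXDC2-1 (left) or siPLXDC2-2 (right), each point a gene, with 8 genes named and a dashed line where both are equal. Most genes lie closer to 0 on the vertical axis, such as Tnf at 6.91 against 2.97 and 2.58, while Id3 lies at 0.19 against 4.99 and 5.07.

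Without PTEN, the siRNAs were compared with siNC to see what the knockdown itself changes. The effects were small beside those of PTEN. With siPLXDC2-1 the strongest gain was in the serpin gene Serpinb9b (1.23 ± 0.20, SE, 4 libraries per group), with the pentose phosphate enzyme gene Taldo1 (1.21 ± 0.10) and Cd300e (1.17 ± 0.18) next. Beside Plxdc2 the strongest losses were in Fxyd2 (-1.27 ± 0.15), the carboxypeptidase gene Scpep1 (-1.18 ± 0.04, and -1.23 with siPLXDC2-2) and the lectin gene Mgl2 (-1.10 ± 0.15). With siPLXDC2-2 the gains were in Lilra6 (2.14 ± 0.15), the itaconate synthase gene Acod1 (1.42 ± 0.17), Itgal (1.21 ± 0.11) and again Taldo1 (1.21 ± 0.10). The losses were in Mgl2 (-1.89 ± 0.16), the chemokine receptor gene Ccr2 (-1.68 ± 0.15) and Plau, which encodes urokinase (-1.46 ± 0.14). Mgl2 stood at 68.1 CPM with siNC, 31.8 with siPLXDC2-1 and 18.4 with siPLXDC2-2.

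With siPLXDC2-1 edgeR called 2448 genes, 1347 higher and 1101 lower, but only 62 changed at least 2-fold. With siPLXDC2-2 it called 3804, 2079 higher and 1725 lower, with 140 changed at least 2-fold. Of 37 genes of IL-4 and IL-13 activation 14 were lower and 1 higher with siPLXDC2-1 (15 and 1 adjusted over the list alone), and 15 lower and 0 higher with siPLXDC2-2 (16 and 2 adjusted over the list alone). They included Clec10a (-0.72 ± 0.11 and -0.83 ± 0.11), Irf4 (-0.89 ± 0.16 and -0.82 ± 0.16), Klf4 (-0.41 ± 0.08 and -0.62 ± 0.08) and Ptgs1 (-0.64 ± 0.07 and -0.21 ± 0.07), and Atp6v0d2 with siPLXDC2-2 (-0.74 ± 0.05) (camera adjusted p = 0.00063 and 0.000222, and with an estimated correlation adjusted p = 0.458 and 0.706). Of 46 ribosomal protein genes 25 and 28 were lower, 0 and 1 higher (31 and 29 lower adjusted over the list alone), with medians of -0.12 and -0.13 (camera adjusted p = 4.62e-08 and 2.77e-06, and with an estimated correlation adjusted p = 0.458 and 0.706). Of 19 NRF2 target genes 6 and 8 were higher (7 and 8 over the list alone), 0 and 1 lower, Taldo1 among the higher (camera adjusted p = 0.00116 and 0.00961, with an estimated correlation adjusted p = 0.694 and 0.706). Type I interferon genes were higher in 11 of 34 cases and lower in 1 with siPLXDC2-1 (camera adjusted p = 0.0266, adjusted p = 0.878 with an estimated correlation).

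With siPLXDC2-1 MHC class II genes were lower in 8 of 13 cases and higher in 1 (10 and 1 adjusted over the list alone), among them the class II transactivator gene Ciita (-0.71 ± 0.08), H2-DMa (-0.50 ± 0.08) and H2-DMb1 (-0.44 ± 0.07), while the protease gene Lgmn was higher (0.21 ± 0.04). The camera adjusted p was 0.000372, and with an estimated correlation the adjusted p was 0.458. Also called were the cell cycle list, with 5 of 42 lower and 1 higher (E2f2 -0.72 ± 0.07, E2f1 -0.57 ± 0.07, Pcna 0.40 ± 0.07; camera adjusted p = 0.00806, adjusted p = 0.878 with an estimated correlation). So were monocyte progenitor markers, with 2 of 7 lower (Cd93 -0.75 ± 0.05, Ccr2 -0.75 ± 0.14) and 1 higher (camera adjusted p = 0.0288, adjusted p = 0.356 with an estimated correlation).

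With siPLXDC2-2 interferon-related genes were higher. These were 29 of 34 type I interferon genes with 0 lower (31 adjusted over the list alone), with a median of 0.25 and Ifit1 (0.56 ± 0.08), Mx2 (0.41 ± 0.06), Bst2 (0.36 ± 0.05) and Ddx58 (0.32 ± 0.04) among them. Of the interferon-gamma and STAT1 targets 22 of 34 were higher and 2 lower, with Tgtp2 (0.63 ± 0.07), Gbp6 (0.57 ± 0.09) and Igtp (0.45 ± 0.06). Of MHC class I genes 14 of 21 were higher (15 over the list alone) and 1 lower, with Tap1 (0.53 ± 0.05) and H2-K1 (0.34 ± 0.06). Of 22 chemokine genes 12 were higher (14 over the list alone) and 2 lower, with Ccl7 at 1.08 ± 0.22. The camera adjusted p-values of these 4 lists were 7.17e-11, 4.18e-05, 0.000661 and 0.0206, and with an estimated correlation each adjusted p was 0.706. Tnf was higher with both siRNAs (0.35 ± 0.09 and 0.52 ± 0.09), and Cd86 (0.65 ± 0.11) and Clec4e (1.00 ± 0.15) with siPLXDC2-2. Pten (-0.05 ± 0.04, adjusted p = 0.428, and 0.02 ± 0.04, adjusted p = 0.691), Plxdc1 (-0.15 ± 0.06, adjusted p = 0.0694, and 0.04 ± 0.06, adjusted p = 0.629) and Nos2 (-0.37 ± 0.24, adjusted p = 0.301, and 0.38 ± 0.21, adjusted p = 0.175) were not called with either siRNA, though Nos2 was with siPLXDC2-2 without siNC PBS replicate 2 (0.66). Plxdc1 was called lower with siPLXDC2-1 by DESeq2 (adjusted p = 0.0466), limma-voom (0.0432), the replicate number as a block (0.0309), only the groups compared (0.0311) and without siNC replicate 2 and siPLXDC2-2 replicate 4 (0.0478).

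Several small effects depended on single PBS libraries or on the fit. With siPLXDC2-2, Stat1 (0.15 ± 0.05, adjusted p = 0.0133) lost its call without replicate 2 of siNC (0.13) or replicate 4 of siPLXDC2-2 (0.09), and Jak2 (0.17 ± 0.06, adjusted p = 0.024) without replicate 2 of siNC (0.13) or replicate 1 (0.12) or 3 (0.15) of siPLXDC2-2. Ptgs1 with siPLXDC2-2 lost it without replicate 2 of siNC (-0.17) or replicate 3 of siPLXDC2-2 (-0.20). With siPLXDC2-1, Mrc1 (-0.17 ± 0.05, adjusted p = 0.0313) lost it without replicate 2 of siNC (-0.12) or replicate 1 (-0.15), 3 (-0.16) or 4 (-0.16) of siPLXDC2-1, while Stat1 (0.11 ± 0.05, adjusted p = 0.0902) and Jak2 (-0.06 ± 0.06, adjusted p = 0.474) were not called. With siPLXDC2-2, Mrc1 was lower (-0.22 ± 0.05, adjusted p = 0.0025). With only the groups compared, Mrc1 (-0.24, adjusted p = 0.0502), Stat1 (0.14, adjusted p = 0.13) and Jak2 (0.15, adjusted p = 0.099) lost their calls with siPLXDC2-2, and Stat1 was called with siPLXDC2-1 (0.11, adjusted p = 0.032), as it was without replicates 2 and 4 of siPLXDC2-2 (adjusted p = 0.018). Of the called genes named for the siRNAs in PBS, Stat1, Jak2, Mrc1 and Ptgs1 with siPLXDC2-2 had libraries that overlapped those of siNC. Without the library farthest from the rest in each group, replicate 2 of siNC and replicate 4 of siPLXDC2-2, the members called higher with siPLXDC2-2 were 25 type I interferon genes, 14 interferon-gamma and STAT1 targets, 8 MHC class I genes and 4 NRF2 genes, and with siPLXDC2-1 there were 5 type I interferon genes. Without replicates 2 and 4 of siPLXDC2-2, the libraries farthest from the rest of their group over all groups, these counts were 30, 22, 12, 7 and 15.

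The 2 siRNAs against the same target were also compared with each other and for the genes they share. In PBS 3354 genes differed between them, 1591 higher and 1763 lower with siPLXDC2-1, and 176 of these at least 2-fold. Plau (2.15 ± 0.14), Serpinb9b (1.97 ± 0.22), Tmx4 (1.45 ± 0.06) and Srsf9, a splicing factor gene (1.42 ± 0.07), were higher with siPLXDC2-1. Gbp2b (-2.27 ± 0.27), Itgal (-1.63 ± 0.11), Lilra6 (-1.47 ± 0.14), Lsp1 (-1.39 ± 0.07) and Acod1 (-1.26 ± 0.17) were higher with siPLXDC2-2 (4 libraries per group). Interferon-gamma and STAT1 targets were lower with siPLXDC2-1 in 21 of 34 cases and higher in 1, and type I interferon genes lower in 19 of 34 and higher in 0 (22 and 23 adjusted over the list alone; camera adjusted p = 1.01e-06 and 2.84e-05, and with an estimated correlation adjusted p = 0.45 and 0.596). MHC class II genes were lower in 8 of 13 cases and higher in 0 (camera adjusted p = 0.00632, adjusted p = 0.45 with an estimated correlation). So were inflammatory genes in 9 of 33, with 0 higher, and cell cycle genes in 9 of 42, with 1 higher (camera adjusted p = 0.0259 and 0.0284, with an estimated correlation adjusted p = 0.596 and 0.744). Immediate-early and heat shock genes (9 higher and 1 lower of 19), matrix genes (9 and 4 of 27) and osteoclast markers (4 and 1 of 9) were called higher with siPLXDC2-1 (camera adjusted p = 0.00861, 0.0347 and 0.00946, and with an estimated correlation adjusted p = 0.305, 0.542 and 0.121).

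Both siRNAs changed 1152 genes in the same direction, 745 up and 407 down, and 199 in opposite directions. Independent lists of these sizes would share 401 in the same direction. Since both comparisons use the same siNC libraries, data simulated with no siRNA effect were run through the same steps. They called a mean of only 0.2 genes for each siRNA. Their 0 shared genes therefore do not tell how far shared control libraries raise the overlap. The simulated log2 changes had a correlation across genes of 0.494, against 0.414 observed (genes are not independent replicates). Their covariance was 0.0144 against 0.0381 observed. With the siNC PBS libraries divided 2 and 2 between the comparisons, a mean of 612 genes was shared in the same direction (565 to 654), against 189 for independent lists. The correlation then had a mean of 0.184.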

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

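Some tests in this part were chosen only after the result was seen. For the PTEN response these were the tests on library scaling and on the protein preparation. All tests on Id3, Smad6 and Id1 were among them. For the type I interferon genes they were those on library scaling and on leaving out 2 PBS libraries together. The same holds for all tests on the difference between the Plxdc2 siRNAs in their PTEN response, the splits included.

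The PTEN response differed between groups by a direct test of the difference in 8013 genes for siPLXDC2-1 against siNC, 8114 for siPLXDC2-2 against siNC, 8501 for the mean of both, and 13 between the Plxdc2 siRNAs. The libraries were also split in other ways and refitted. In each case the real split alone, 1 of 35 (or of 100 for the mean of both), gave as many genes. The highest other split gave 0 genes for siPLXDC2-1, 0 for siPLXDC2-2, 38 for the mean of both and 0 between the Plxdc2 siRNAs. For these response differences whole title stems were moved between siRNAs that also differed in PBS. That difference widens the spread within the groups of every other split. These splits therefore cannot exclude chance for the response differences. For PTEN against PBS the highest other split gave 4 genes in place of 9673 under siNC and 1 in place of 5545 under siPLXDC2-1. Under siPLXDC2-2 it gave 390 in place of 5580. In PBS it gave 118 in place of 2448 for siPLXDC2-1 and 270 in place of 3354 between the Plxdc2 siRNAs. For PTEN against PBS and these PBS comparisons chance can be excluded only if the libraries of a comparison are interchangeable. Same-number pairs correlated on average there too (means of 0.162 to 0.25). The means for different numbers (-0.08 to -0.052) take the opposite sign through the centring of residuals within groups. If the numbers pair the libraries, the splits that part all pairs are too few to exclude chance. For siPLXDC2-2 against siNC in PBS all 4 same-number pairs correlated above 0.1, so the replicate numbers may pair the libraries. If they do, the 8 splits that part all 4 pairs are too few for a share under 0.05. The real one gave 3804 genes and the highest other 281, and a split that parts 2 of the pairs gave 1602.

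Single libraries stood far from the other 3 of their group in 8 of 138 groups of values examined, where chance gives about 5%, or 6.9. They were Plxdc2 at 12.7 CPM in replicate 2 of siPLXDC2-2 PBS (others 5.42 to 6.64) and Nos2 at 2.9 CPM in replicate 2 of siNC PBS (others 1.49 to 1.59). Il10 was at 4.65 CPM in replicate 1 of siNC PBS (others 5.72 to 5.93), and Cd86 at 193 CPM in replicate 4 of siNC PTEN (others all 204). Il12b was at 745 CPM in replicate 2 of siNC PTEN (others 439 to 485) and at 0.149 CPM in replicate 1 of siPLXDC2-2 PBS (others 0.253 to 0.258). Replicate 2 of siPLXDC2-1 PTEN had 9.66% of its counts in its top 10 genes (others 9.32% to 9.37%) and 1.04% in mitochondrial genes (others 0.905% to 0.921%).

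The first pattern weighed is the smaller PTEN response under both Plxdc2 siRNAs. Library scaling as the cause needs most of the response back under another scaling. The highest share kept over 3 scalings was 23.77% for called genes of both directions together, where a shift of all genes partly cancels. With the directions apart the highest share was 30.99%, for genes that rose with library totals alone, and 20.25% for genes that fell there. Genes already moved in PBS would have to account for much of the lost response, and their shift toward the PTEN level was 6.43% of it. The part of a component of the protein preparation that acts without Plxdc2 stays open: the higher of the arms kept 24.5% of the response, which restates the pattern, and the design has no control for such a component. Lower Plxdc2 could also change the sensitivity of the cells to it, and the remaining response may come from remaining Plxdc2 or from another route.

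The second pattern is the rise of Id3, Smad6 and Id1 with PTEN under both Plxdc2 siRNAs, with no call under siNC (0.19, -0.39 and 0.65, adjusted p = 0.353, 0.451 and 0.161). The smallest log2 change over both arms was 4.04, and for 3 of 3 genes the lowest siPLXDC2 PTEN library (47.5 CPM for Id3, 11 for Smad6, 2.15 for Id1) lay above the highest of the others (3.65, 0.818 and 0.341). Since the genes were chosen for such a rise, these values restate the pattern, and neither an off-target effect of 1 siRNA nor a single library was tested by them. A candidate explanation is a wider response of SMAD target genes that rise together: of 4 other such genes tested 1 rose in both arms, Id2 (0.89 and 0.96), but it also rose under siNC (0.57, adjusted p = 9.19e-10), where Smad7 (-1.89, but 0.72 under siPLXDC2-2) and Hey1 (-3.20) fell. Id2 was the only one of the 4 at 5 CPM or more in a group, so this and a change limited to a few genes cannot be told apart.

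The third pattern is the higher level of type I interferon genes under siPLXDC2-2 than under siNC in PBS. Libraries that stand apart are argued against as the cause, since 25 of 34 members were called higher without replicate 2 of siNC and replicate 4 of siPLXDC2-2, and 30 without replicates 2 and 4 of siPLXDC2-2. So is library scaling, which moves every gene of a library alike: beyond the median gene the list shifted by 0.26, with SDs between libraries of 0.082 and 0.1. The highest siNC library lay at -0.043 and the lowest siPLXDC2-2 library at -0.011. The exact permutation p of 0.0286 ignores a possible pairing of these libraries by number. The list was also weighed because its members were already called higher here, so this p adds no evidence. A difference between the Plxdc2 siRNAs is what 19 of 34 members called lower under siPLXDC2-1 than under siPLXDC2-2 would need. An effect of siPLXDC2-2 beyond Plxdc2 may therefore contribute, and since the siRNA sequences are not given and each siRNA had a single set of libraries, the siRNA and its set of libraries both stay open.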

How the results depend on the processing

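In this part the tests chosen only after the result was seen are library totals alone for the gene lists and the kept share, leaving out 2 PBS libraries together, and all alternatives for the 13 genes that differ between the Plxdc2 siRNAs in their PTEN response.

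The 9 counts of genes planned as comparisons stayed within 1.5 times their value under every alternative run. With each library left out in turn, genes called for PTEN ranged from 9525 to 9611 under siNC, 5003 to 5218 under siPLXDC2-1 and 5120 to 5614 under siPLXDC2-2. Response differences ranged from 7820 to 7932, 7928 to 8149 and, for the mean of both, 8282 to 8615. In PBS the ranges were 1947 to 2397 for siPLXDC2-1, 3157 to 4109 for siPLXDC2-2 and 2868 to 3491 between them, and Plxdc2 ranged from -4.20 to -4.06 and from -4.31 to -3.80.

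The 13 genes became 44 with DESeq2, 49 with the replicate number as a block and 52 with the title stem as a block, and ranged from 7 to 22 with a library left out: 8 without replicate 2 of siPLXDC2-1 PTEN or replicate 4 of siPLXDC2-1 PBS, 22 without replicate 2 and 7 without replicate 3 of siPLXDC2-2 PTEN. The cause was not tested.

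Gene lists called for PTEN under siNC numbered 7, and 7 to 7 with a library left out, but 3 with an estimated correlation and 25 with fry. An estimated correlation widens the null spread of a list where it exceeds the preset 0.01. It was 0.359 to 0.514 in the lists that lost their call. By construction fry tests a list against no change in place of against other genes. The share of the response kept was 23.8%, and 37.09% in the 100 genes of smallest p, with medians of 1.72 and 1.61; the cause was not tested. Shared genes of both siRNAs in PBS numbered 1152, and 611.7 with the siNC libraries divided, where each comparison has fewer libraries.

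Plxdc2 under siNC reversed with library totals alone, from 0.08 to -0.391 (adjusted p = 0.00458), a change close to the -0.47 by which that scaling moves all genes. Of 6391 alternative values of 305 named-gene results 6339 kept direction and call, 30 lost the call, 21 gained it and 1 reversed. Of 812 for the 28 lists 787 kept both, 5 lost the call and 20 gained it.

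For the mean of both siRNAs, using only the groups compared gives the fit already reported and so no value. Depth limits genes with few reads: Il12a had 2 reads in siNC PBS, which leaves its fold between 740 and 22100.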

Other observations

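In this part all values were chosen only after they were seen, and no explanation was tested.

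Genes of IL-4 activation stood at very different levels in siNC cells with PBS. Retnla was at 1118 CPM and Mrc1 at 826 CPM, while Arg1 was at 0.580 CPM, Ccl24 at 0.0598 CPM and Ccl17 at 0.0102 CPM.

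Irf4, a transcription factor gene, fell with PTEN by nearly the same amount in all arms: the log2 change was -1.40 under siNC, -1.37 under siPLXDC2-1 and -1.41 under siPLXDC2-2, and no difference was called (0.01 for the mean of both, adjusted p = 0.967).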
